A study of Mus musculus with 7 samples.

How the data were processed

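Messenger RNA levels were measured by RNA sequencing in 7 mouse spleen libraries, 3 from spleens given phosphate-buffered saline (PBS) and 4 from spleens remodelled with a biomaterial that the labels call sHA-X. All spleens were taken 30 days after hepatocytes, the main cells of the liver, had been injected into them. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were built with the VAHTS Universal V6 kit. Whether the kit kept the strand of the RNA is not given in the sources used here, so reads of overlapping genes on opposite strands cannot be told apart. The submitters' processing notes name fastp, HISAT2, HTSeq, DESeq2, R 3.2.0 and the mouse genome build mm10, without their roles.

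The deposited table held 1 value per gene and library for 22173 genes. Its header did not name the unit. The values were read as FPKM (fragments scaled to transcript length and to library size) that the authors computed, because within a gene they were whole multiples of a step that depends on the gene, and the steps of different libraries stood in a fixed ratio. A value in the deposited FPKM table was called whole when it lay within 0.05 of a read. By this test whole reads were recovered for all 16889 genes above 0 in at least 2 libraries. The 704 genes above 0 in only 1 library were not recovered. For a gene above 0 in few libraries, whole numbers can be found by chance, and the smallest that fitted were taken. The recovered totals were 32048921, 31809882 and 33322869 reads for PBS replicates 1 to 3, and 31804492, 29543963, 33307896 and 37142126 for sHA-X replicates 1 to 4. The deepest library had 1.26 times the reads of the shallowest, and total ratios and step ratios differed by at most 0.07%. The recovery was tested on 6000 simulated genes and returned 100.0% of them, up to a factor common to all values of a gene. Values of 0 in the table stand for 0 reads. Near-identical paralogs, such as major urinary protein genes, trypsinogens and class I histocompatibility genes, may share reads and are uncertain as single genes. Immunoglobulin and T cell receptor constant genes and mitochondrially encoded genes were not analysed here.

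The test planned for raw counts did not suit FPKM, so the fallback that had been fixed before the data were examined was used. Values were tested as log2(FPKM + 1) with limma 3.58.1 (trend and robust variance) in R 4.3.3, with the group as the only term. Genes with a mean under 1 FPKM over the 7 libraries were left out. This kept 11920 genes and left out 10253. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. A fold change on the log2(FPKM + 1) scale understates the change of genes with low values. The labels give 3 and 4 as the group sizes without saying that each library came from a separate animal, so p-values measure only the spread between these libraries. In a simulation on the 11920 genes of this comparison with 200 changed genes, 87% of 2-fold and 97% of 4-fold changes were recovered, and 12 of 196 calls were false. The simulated noise was independent between genes and between libraries, so these rates may not hold where genes or libraries deviate together.

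A total of 42 gene lists for hepatic functions, tissue remodelling, cell types and processes were fixed at the same time, and 41 had at least 5 tested members. They were tested on the log2(FPKM + 1) values, in place of the planned log2 counts, with limma's camera (two-sided, preset correlation of 0.01 between genes, adjusted over the lists), with camera at an estimated correlation, and with fry. Genes of a list are correlated, and with the correlation estimated from these libraries camera called 0 of the 41 lists (4 at an unadjusted p under 0.05), against 19 higher and 7 lower with the preset one and 16 with fry. Pathway names in the deposited table gave 309 further sets of 10 to 300 tested genes. Single values per library, such as the summed FPKM of a list (in place of the planned share of counts), were compared by a two-sided exact permutation test over all 35 splits of the libraries into 3 and 4, for which the smallest possible p is 0.0286. Gene coordinates are those of the RefSeq annotation of GRCm38 (mm10), matched by the NCBI gene identifiers in the table.

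The genes named were set by a rule fixed in advance. It took the 12 largest rises and 12 largest falls among called genes with a mean of at least 1 on the log2 scale and no overlap between the groups, up to 4 members with the smallest p of each called list and of the 4 lists that the study's design names, and 32 genes named whatever their values. The rule's threshold had been written for log2 CPM and was applied to log2(FPKM + 1). Some genes that the rule names are not reported here. Other genes are said to have been chosen after their values were seen, or are named as the called members of a list. Alternatives were another pseudocount, other filters, other scalings, fits without robust variance, thresholds on the fold, each library left out in turn, the replicate number as a block, and limma-voom with quality weights on the recovered reads. Library totals are already the deposited scaling, so that alternative had no separate fit. Of the planned count tools only limma-voom was run. Left-out fits were also made for all called list members that are named. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for read recovery and plots.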

Results

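RNA sequencing of 7 mouse spleen libraries addressed whether a spleen remodelled with sHA-X and then injected with hepatocytes differs from a PBS-treated spleen in genes of drug, glucose, fatty acid and cholesterol metabolism 30 days after the injection. There were 3 PBS libraries and 4 sHA-X libraries, with between 29543963 and 37142126 recovered reads each. Values are FPKM, given as mean ± SD with n = 3 for PBS and n = 4 for sHA-X.

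Spleens of the sHA-X group had higher levels of many genes of the cytokine and chemokine, extracellular matrix and macrophage lists than PBS spleens, and lower levels of many B cell and platelet genes, by counts of single genes. As whole lists, these 5 had an adjusted p between 0.40 and 0.64 by camera with an estimated correlation. Fry called all 5 in these directions (adjusted p between 0.0040 and 0.018). The summed FPKM of each had the smallest possible exact permutation p, 0.0286 (0.11 adjusted over the lists). Of 11920 genes tested with limma, 1108 were higher and 600 lower in sHA-X at an adjusted p under 0.05. At least 2-fold changes on the log2(FPKM + 1) scale were fewer, with 138 higher and 13 lower. The groups did not overlap for 28.8% of genes, where chance gives 5.7%. Ccl8, a monocyte-attracting chemokine (NCBI gene 20307, chromosome 11, 82115185 to 82116799), was 0.501 ± 0.286 FPKM in PBS and 59.9 ± 25.6 FPKM in sHA-X, a log2 change of 5.28 (SE 0.33, adjusted p = 0.00066 by limma). Wfdc17 was 7.09-fold higher by the ratio of means (21.4 ± 1.13 and 151.5 ± 34.7 FPKM). The matrix metalloproteinase gene Mmp3 was 14.9-fold higher, the matrix protein gene Mgp 5.14-fold and the apolipoprotein gene Apod 18.3-fold. Among the largest falls, Niban3 went from 18.02 ± 0.24 to 5.58 ± 0.49 FPKM, and Siglech, a plasmacytoid dendritic cell marker, from 20.8 ± 1.95 to 8.34 ± 1.05 FPKM. Il22ra2 and Aplnr, which encodes the apelin receptor, also fell. The 12 largest falls also held the elastin gene Eln, Gdf6, Atp1b1, Cd300c, Tesc, Ear1, Ear6 and the haemoglobin gene Hba-a2. The calls of Ear1 (without PBS replicate 2 or sHA-X replicate 1), Ear6 (without PBS replicate 1 or 2 or sHA-X replicate 1 or 3) and Hba-a2 (without each library except sHA-X replicate 3) were lost, with adjusted p up to 0.058, 0.098 and 0.14. The 12 largest rises also held Saa3, Cxcl14, Ms4a6d, Lyve1, Lum, Spp1 and Ccl7. Saa3, an acute phase gene, was 124.4, 5.33, 33.5 and 24.2 FPKM in sHA-X replicates 1 to 4 and at most 0.0585 FPKM in PBS, and its call was lost without any PBS library or without sHA-X replicate 3 or 4 (adjusted p up to 0.11). That of Cxcl14 was lost without any PBS library or without sHA-X replicate 1 or 3 (adjusted p up to 0.096). Fits with 1 library left out hold fewer values, so a lost call can reflect less power as well as dependence on that library. The number of calls nonetheless differed with the library left out, and rose to 1263 higher and 637 lower without PBS replicate 3. It was 488 higher and 228 lower without PBS replicate 1, 718 higher without PBS replicate 2, 712 higher and 351 lower without sHA-X replicate 4, 342 lower without sHA-X replicate 1 and 345 lower without sHA-X replicate 3. PBS replicate 2 carried pancreatic acinar genes and sHA-X replicate 2 skeletal muscle genes, and leaving out both gave 492 higher and 330 lower genes.

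Genes restricted to hepatocytes were high in sHA-X replicates 3 and 4 and low in the other 5 libraries. Albumin (Alb) was 0.271, 4.10 and 1.15 FPKM in PBS replicates 1 to 3, and 2.17, 8.49, 325.3 and 370.4 FPKM in sHA-X replicates 1 to 4. Apoa1, the main protein of high-density lipoprotein, was 0.634, 4.504, 155.4 and 141.6 FPKM in sHA-X replicates 1 to 4, against at most 1.33 FPKM in PBS. Ttr, the thyroid hormone carrier transthyretin, was 0.214, 1.33, 49.2 and 40.97 FPKM in sHA-X. Because the 4 sHA-X libraries spread this widely, the group difference did not pass limma for Alb (log2 change 4.18, SE 2.03, adjusted p = 0.24), Apoa1 (adjusted p = 0.26) or Ttr (adjusted p = 0.32). The summed FPKM of 50 hepatocyte identity and plasma protein genes was 156.7, 154.9 and 162.9 in PBS and 252.4, 245.7, 1737 and 1822 in sHA-X (exact permutation test, two-sided, p = 0.17). Trf, the transferrin gene, alone gave 130.4, 115.1 and 135.7 FPKM of the sum in PBS. In sHA-X it gave 215.7, 179.0, 304.7 and 268.6 FPKM. Trf was thus most of the sum in each library except sHA-X replicates 3 and 4. Of the list's 36 tested members only Trf rose, by limma adjusted over all genes and adjusted over the list alone. Trf is also in the macrophage list, and its call was lost without PBS replicate 1, PBS replicate 2 or sHA-X replicate 4 (adjusted p up to 0.072). The list was called higher by camera (adjusted p = 2.7e-05), with adjusted p = 0.67 with an estimated correlation and 0.19 by fry.

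**Figure D1:**
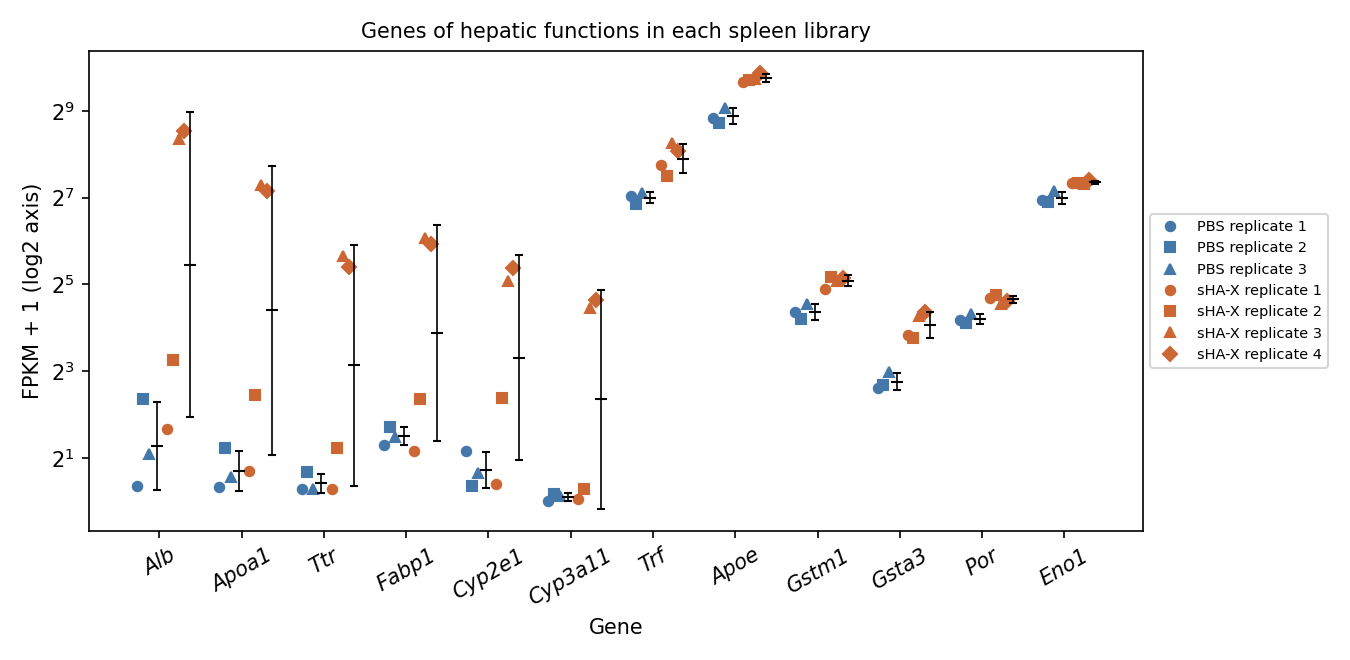
FPKM + 1 on a log2 axis for 12 genes of hepatic functions, with 1 point per library and the mean ± SD of the log2 values in black (n = 3 PBS, n = 4 sHA-X). Alb, Apoa1, Ttr, Fabp1, Cyp2e1 and Cyp3a11 stand high only in sHA-X replicates 3 and 4, whereas Apoe, Gstm1, Gsta3, Por, Eno1 and Trf are higher in each sHA-X library than in each PBS library.

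Of the drug metabolism list, 6 of 32 tested members rose, none fell and 26 did not pass, both over all genes and adjusted over the list alone. The 6 were the glutathione transferases Gsta3, Gstm1 and Gstp1, the flavin monooxygenase Fmo1, the cytochrome P450 reductase Por and the aldehyde dehydrogenase Aldh2. Gsta3 (NCBI gene 14859, chromosome 1, 21240565 to 21265575) was 5.78 ± 0.94 FPKM in PBS and 15.9 ± 3.53 FPKM in sHA-X (adjusted p = 0.0036 by limma), Gstm1 19.7 ± 2.54 and 32.9 ± 2.87 FPKM, and Por 17.4 ± 1.49 and 24.2 ± 1.5 FPKM. The calls of Gstp1 (without PBS replicate 1 or 2 or sHA-X replicate 1, 3 or 4) and Aldh2 (without each library except PBS replicate 3) were lost, with adjusted p up to 0.17 and 0.095. The hepatic cytochromes P450 Cyp2e1, Cyp3a11 and Cyp1a2 did not pass. Cyp2e1 was 0.320, 4.19, 33.0 and 40.5 FPKM in sHA-X replicates 1 to 4 and up to 1.24 FPKM in PBS (adjusted p = 0.27 by limma). Cyp3a11 was 20.8 and 23.8 FPKM in sHA-X replicates 3 and 4 and at most 0.214 FPKM elsewhere (adjusted p = 0.36). Cyp1a2 reached 6.15 and 6.36 FPKM in those 2 libraries (adjusted p = 0.31). Camera called the list higher (adjusted p = 2.7e-05), with adjusted p = 0.64 with an estimated correlation and 0.061 by fry.

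Of the glucose metabolism list, 2 of 18 tested members rose, 1 fell and 15 did not pass, with the same counts adjusted over the list alone. Pygl, the liver-type glycogen phosphorylase, was 17.7 ± 0.31 FPKM in PBS and 23.7 ± 1.71 FPKM in sHA-X (adjusted p = 0.0064 by limma). The glycolytic enzyme Eno1 was 127.0 ± 12 and 162.0 ± 4.17 FPKM (adjusted p = 0.014, and 0.068 without PBS replicate 1, where 1 member rose). Foxo1, a transcription factor of gluconeogenesis, fell from 28.9 ± 2.42 to 21.8 ± 1.74 FPKM (adjusted p = 0.016). Pgm1 did not pass (adjusted p = 0.074). G6pc, the glucose-6-phosphatase that releases free glucose, was 4.51 and 4.63 FPKM in sHA-X replicates 3 and 4 and at most 0.134 FPKM elsewhere (adjusted p = 0.35). Pck1, an enzyme of gluconeogenesis, was 0.0119, 2.83, 6.38 and 6.62 FPKM in sHA-X and up to 0.680 FPKM in PBS (adjusted p = 0.25), and Pklr did not pass (adjusted p = 0.30). In sHA-X replicate 2 the adipocyte list stood highest, with a sum of 146.1 FPKM against 42.1 to 100.9 FPKM elsewhere. The source of Pck1 in that library was not tested. Camera gave adjusted p = 0.028 in the higher direction, with adjusted p = 0.64 with an estimated correlation and 0.029 by fry. The camera call was lost without PBS replicate 2 (adjusted p = 0.071), sHA-X replicate 3 (0.062) or sHA-X replicate 4 (0.061).

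Of the fatty acid metabolism list, 6 of 38 tested members rose, none fell and 32 did not pass, with the same counts adjusted over the list alone. Dgat2, which makes triglycerides, was 3.54 ± 0.57 FPKM in PBS and 8.94 ± 0.93 FPKM in sHA-X (log2 change 1.13, SE 0.11, adjusted p = 0.00074 by limma). The members that rose also included Acsl5, Acaca, Fads1 and Fads2, each with a call lost in 3 to 6 of the 7 fits with 1 library left out (adjusted p up to 0.067, 0.10, 0.12 and 0.12). Fabp1, the fatty acid carrier of hepatocytes, was 1.22, 4.15, 65.8 and 60.1 FPKM in sHA-X and up to 2.26 FPKM in PBS (adjusted p = 0.33). Fasn (adjusted p = 0.54) and Cpt1a (adjusted p = 0.41) did not pass. Only 1 member rose without PBS replicate 1 or without sHA-X replicate 4, 2 without sHA-X replicate 3, 3 without sHA-X replicate 1 or 2, and 4 without PBS replicate 2. Camera called the list higher (adjusted p = 0.0016), with adjusted p = 0.43 with an estimated correlation and 0.011 by fry.

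Of the cholesterol and bile acid list, 7 of 35 tested members rose, 1 fell and 27 did not pass, with the same counts adjusted over the list alone. Apoe, a lipoprotein gene that macrophages also express (NCBI gene 11816, chromosome 7, 19696244 to 19701310), was 470.1 ± 62.0 FPKM in PBS and 859.8 ± 55.6 FPKM in sHA-X (adjusted p = 0.0012 by limma). Hsd3b7, an enzyme of bile acid synthesis, was 7.50 ± 0.95 and 11.2 ± 1.04 FPKM, and Soat2, a cholesterol esterifying enzyme, 1.09 ± 0.26 and 2.04 ± 0.12 FPKM. Scarb1, Abca1, Fdps and Cyp7b1 also rose. Calls were lost for Hsd3b7 without PBS replicate 1 (adjusted p = 0.051), for Scarb1 without PBS replicate 2 (0.052), for Fdps and Cyp7b1 without PBS replicate 1 or 2 (up to 0.089 and 0.090), and for Abca1 also without sHA-X replicate 1 or 3 (up to 0.070). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was under the filter at no more than 0.103 FPKM in any library. Without PBS replicate 1 or 2, 3 members rose, and 1 without both PBS replicate 2 and sHA-X replicate 2. Camera called the list higher (adjusted p = 0.0040), with adjusted p = 0.64 with an estimated correlation and 0.073 by fry. The summed FPKM of the glucose and cholesterol lists each had exact permutation p = 0.0286 (0.11 adjusted over the lists). Those of the drug and fatty acid lists each had 0.086 (0.19 adjusted). Over the drug, glucose, fatty acid and cholesterol lists, 21 of 123 tested members rose. Of these 21, 19 (90.5%) had a PBS mean of at least 1 FPKM, as did 70.7% of all tested members. Most genes that rose were thus also present in PBS spleens, which does not show the source of the rise. Of the 36 members under 1 FPKM in PBS, which the filter kept only for their sHA-X values, 34 did not pass.

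In other liver lists, some complement genes rose and hepatocyte genes again stood high in sHA-X replicates 3 and 4. In the complement and acute phase list 10 of 21 tested members rose, none fell and 11 did not pass. Lrg1 was 15.1 ± 1.17 FPKM in PBS and 50.6 ± 3.92 FPKM in sHA-X. The complement genes C4b, C6, C3, C1ra, C1s1 and Cfb and the acute phase genes Hp and Lbp were also among the members that rose. The calls of C3, Hp and Cfb were lost in 5, 4 and 1 of the 7 fits with 1 library left out, with adjusted p up to 0.11, 0.070 and 0.050. The list was called higher (camera adjusted p = 9.7e-09, and adjusted p = 0.40 with an estimated correlation). Of 14 coagulation genes only Pros1 rose. Fgb, a fibrinogen chain, was 54.0 and 57.4 FPKM in sHA-X replicates 3 and 4 and at most 1.21 FPKM elsewhere. The coagulation list (camera adjusted p = 0.022, and adjusted p = 0.68 with an estimated correlation), the periportal list (0.0023 and 0.64, with 1 of 13 members risen, Ctsc) and the male-biased liver list (0.0023 and 0.64, with Cyp7b1, C6 and Gstp1 risen of 12) were called higher. Only 1 male-biased gene rose without PBS replicate 1 or 2, and the coagulation call was lost without PBS replicate 3 (0.057), sHA-X replicate 3 (0.16) or sHA-X replicate 4 (0.15). The coagulation call was also lost with the filter of 1 CPM in 3 libraries and 50 reads. Fry called the complement and acute phase list higher (adjusted p = 0.0016). It did not call the coagulation (adjusted p = 0.24), periportal (0.073) or male-biased (0.073) list. The summed FPKM of the complement and acute phase list had exact permutation p = 0.0286 (0.11 adjusted over the lists). Not called were the urea cycle and amino acid list (adjusted p = 0.081, 2 risen and 2 fallen of 23) and the pericentral list (adjusted p = 0.15, 1 risen of 13). Afp, a marker of fetal liver, did not pass (adjusted p = 0.86), and the fetal liver list was not called (adjusted p = 0.83, with Epcam and Spp1 risen of 8, a median log2 change of -0.10 and a mean of 0.37), although fry called it higher (adjusted p = 0.022).

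Most of the extracellular matrix genes tested rose. Of 51 tested members 33 rose, 4 fell and 14 did not pass, and 37 rose and 5 fell adjusted over the list alone. Lum, a collagen-binding proteoglycan (NCBI gene 17022, chromosome 10, 97565501 to 97572703), was 0.796 ± 0.443 FPKM in PBS and 16.1 ± 5.21 FPKM in sHA-X (log2 change 3.23, SE 0.30, adjusted p = 0.0018 by limma). Col6a2 was 3.42 ± 0.60 and 9.35 ± 1.23 FPKM, and the crosslinking enzyme Loxl1 4.74 ± 0.63 and 10.7 ± 1.36 FPKM. Col1a1 was 18.96 ± 2.38 and 57.3 ± 20 FPKM, a call lost without PBS replicate 1 or 2 (adjusted p up to 0.058). Col3a1 was 2.502-fold higher, a call lost without any PBS library or without sHA-X replicate 3 or 4 (adjusted p up to 0.086). The members that fell were the elastin gene Eln (24.1 ± 5.92 to 7.56 ± 0.82 FPKM), the basement membrane collagens Col4a1 and Col4a2, and Fbln5. The call of Fbln5 was lost without PBS replicate 1 (adjusted p = 0.064) and that of Col4a2 in 5 of the 7 fits (up to 0.12), and 2 members fell without PBS replicate 1. Camera gave adjusted p = 1.2e-09, and adjusted p = 0.64 with an estimated correlation, and fry gave 0.018. In the fibroblast list 9 of 21 members rose, among them Pi16 (2.25 ± 0.31 to 9.21 ± 1.66 FPKM) and Dcn, and Cxcl13 fell, a call lost in 5 of the 7 fits (adjusted p up to 0.10). Camera gave adjusted p = 0.0071, with adjusted p = 0.64 with an estimated correlation and 0.055 without both second libraries. By fry the adjusted p was 0.029. Without PBS replicate 1 or 2, 5 and 4 members rose. The TGF-beta list was not called (adjusted p = 0.19, with 6 risen and 1 fallen of 34, and 2 fallen adjusted over the list alone). Tgfb1 was 94.1 ± 5.31 and 87.8 ± 8.06 FPKM (adjusted p = 0.45 by limma) and Ccn2 did not pass (adjusted p = 0.46).

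**Figure D2:**
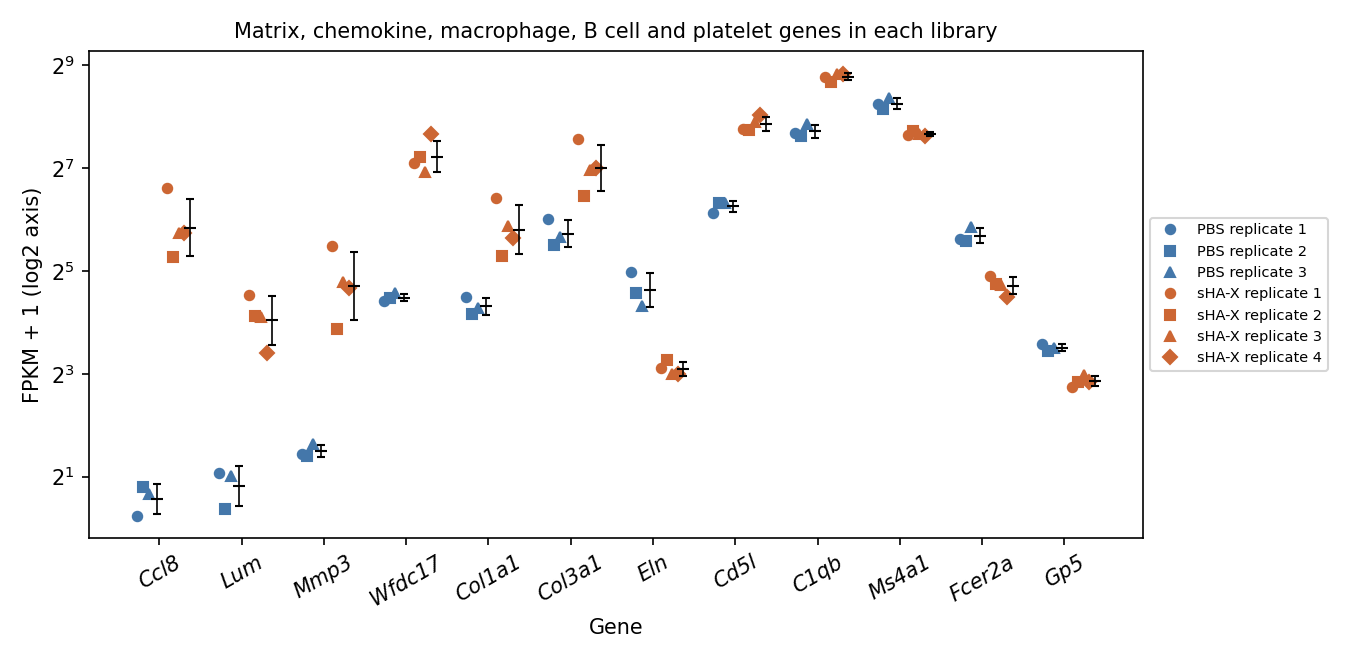
FPKM + 1 on a log2 axis for 12 matrix, chemokine, macrophage, B cell and platelet genes, with 1 point per library and the mean ± SD of the log2 values in black (n = 3 PBS, n = 4 sHA-X). Ccl8 to Col3a1 and Cd5l and C1qb lie higher in each sHA-X library than in each PBS library, and Eln, Ms4a1, Fcer2a and Gp5 lie lower.

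Most of the macrophage genes tested rose, and most of the B cell and platelet genes fell. Of 26 macrophage genes 17 rose, none fell and 9 did not pass. Cd5l was 75.8 ± 5.69 FPKM in PBS and 232.1 ± 23.3 FPKM in sHA-X, the complement gene C1qb 209.7 ± 18.2 and 439.3 ± 20.4 FPKM, and Spic, a transcription factor of red pulp macrophages, 73.3 ± 8.91 and 108.5 ± 5.93 FPKM (adjusted p = 0.0049 by limma). In the monocyte and neutrophil list 10 of 25 rose, among them Il1b and Csf3r, and in the mast cell list 7 of 10, among them the proteases Tpsb2 (0.108 ± 0.019 to 2.27 ± 0.50 FPKM) and Mcpt4. Without PBS replicate 2, 4 mast cell genes rose. In the cytokine and chemokine list 12 of 23 rose. Besides Ccl8 they included Ccl12 (0.519 ± 0.181 to 6.01 ± 1.55 FPKM), and Ccl7 and Spp1, whose calls were lost in 6 and 5 of the 7 fits with 1 library left out (adjusted p up to 0.12 and 0.081). Without PBS replicate 1 or 2, 5 and 6 members rose. Of 18 B cell genes 12 fell, none rose and 6 did not pass. Ms4a1 went from 304.8 ± 21.9 to 201.6 ± 5.31 FPKM, Cd79b from 504.9 ± 50.4 to 322.2 ± 25.0 FPKM and Fcer2a from 50.5 ± 5.34 to 25.4 ± 2.96 FPKM. Of 20 megakaryocyte and platelet genes 13 fell, none rose and 7 did not pass, with Gp5 at 10.4 ± 0.58 and 6.25 ± 0.47 FPKM. Camera gave adjusted p = 1.2e-09 for macrophages, 1.1e-05 for monocytes and neutrophils, 0.0040 for mast cells, 5.5e-08 for cytokines, 6.4e-11 for B cells and 7.5e-10 for megakaryocytes. With an estimated correlation the adjusted p of these 6 lists was between 0.40 and 0.44, and by fry between 0.0016 and 0.011. Adjusted over the list alone, 18 macrophage, 14 monocyte and neutrophil, 7 mast cell and 16 cytokine genes rose, and 14 B cell and 14 megakaryocyte genes fell.

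Camera also called lists of other immune cells lower. Among T cell genes 3 of 24 fell, Lef1, Ccr7 and Cd8a, and among NK cell genes 2 of 15, Klra4 and Klra9. Of 16 dendritic cell genes 4 fell, including Siglech and Clec9a, and Bst2 rose. Adjusted over the list alone, 3, 5 and 5 members of the T cell, NK cell and dendritic cell lists fell. The calls of Ccr7, Cd8a and Klra9 were lost in 5 of the 7 fits with 1 library left out and that of Bst2 in 3 (adjusted p up to 0.084, 0.10, 0.14 and 0.094). T cell genes that fell numbered 1 without PBS replicate 1 or sHA-X replicate 1 or 2, and NK cell genes 1 without PBS replicate 1 or 3 or sHA-X replicate 4. Camera called these 3 lists lower (adjusted p = 3.0e-04, 0.028 and 7.4e-04, and adjusted p = 0.64, 0.64 and 0.59 with an estimated correlation), and fry gave 0.26, 0.27 and 0.024. PBS replicate 3 stood highest, with T cell sums of 537.2, 534.8 and 714.6 FPKM in PBS replicates 1 to 3 and 449.8 to 548 FPKM in sHA-X (exact permutation p = 0.11), and NK cell sums of 269.2, 279.5 and 352.9 FPKM and 274.5 to 301.6 FPKM (exact permutation p = 0.66). The same library had an erythroid sum of 26705 FPKM against 55652 and 53055 FPKM in PBS replicates 1 and 2. The sHA-X libraries ranged from 19962 to 31756 FPKM, so PBS replicate 3 lay within their range. The NK cell call was lost without PBS replicate 3 (0.27) or sHA-X replicate 1 (0.059). The endothelial, smooth muscle, stellate cell, cholangiocyte, adipocyte, mesothelium, angiogenic factor, erythroid and cell cycle lists were not called by camera (adjusted p = 0.58, 0.67, 0.13, 0.25, 0.28, 0.97, 0.97, 0.10 and 0.97). In the stellate cell list 4 of 10 genes rose and 1 fell, and in the cholangiocyte list 3 of 7 rose, and fry called both higher (adjusted p = 0.020 and 0.0016). Of the endothelial and angiogenic factor lists 4 genes each rose and 2 each fell, and adjusted over the list alone 4 and 6 rose and 2 and 5 fell. None of 30 cell cycle genes passed limma, and 0 had an unadjusted p under 0.05. Mki67 was 112.9, 145.0 and 39.8 FPKM in PBS and 77.7 to 106.5 FPKM in sHA-X (adjusted p = 0.95). Pancreatic acinar genes summed to 1535 FPKM in PBS replicate 2 and to at most 36.8 FPKM elsewhere, and skeletal muscle genes to 273.1 FPKM in sHA-X replicate 2 and to at most 24.6 FPKM elsewhere.

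**Figure D3:**
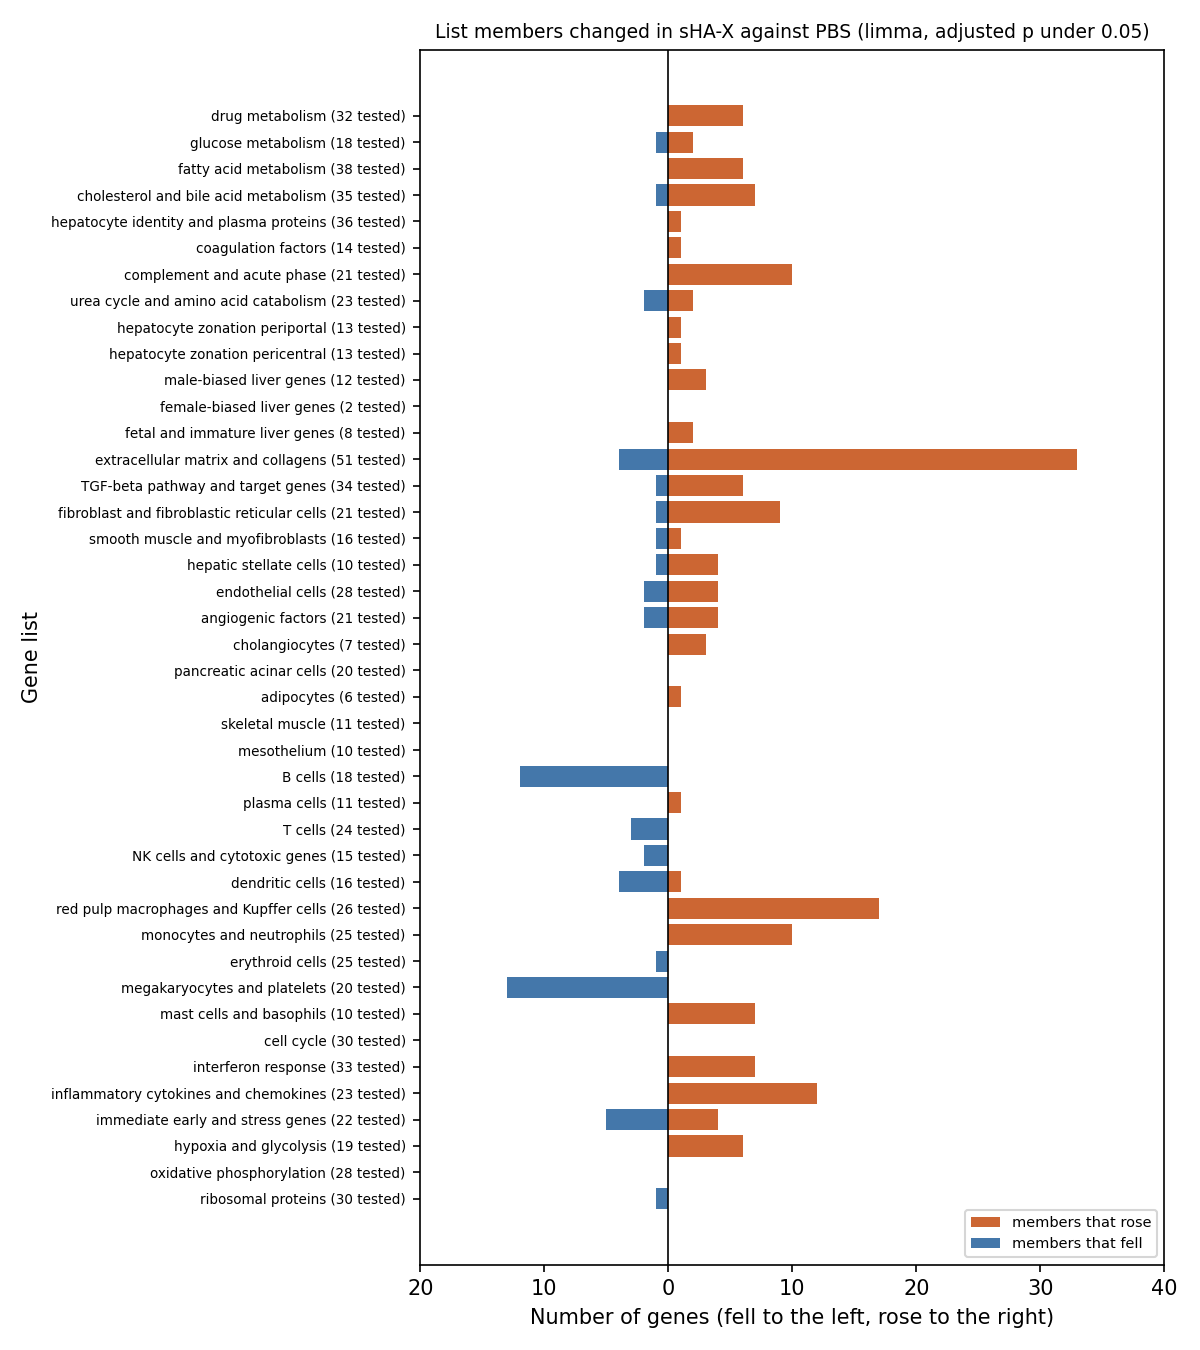
Number of members of each of the 42 lists that rose (right) or fell (left) in sHA-X against PBS by limma at an adjusted p under 0.05. The extracellular matrix list has 33 members that rose and 4 that fell, and the B cell list has 12 that fell.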

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

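Within the 4 sHA-X libraries, 196 values (42 list sums and the named genes) were checked for a library that stands apart from the other 3. There were 8, where chance alone gives about 9.8. Each number in brackets is the gap of that library to its nearest neighbour as a share of the range of the 4. The tests in this part were chosen after the values were seen.

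Replicate 2 stood apart for skeletal muscle genes (0.983), with a sum of 273.1 FPKM against 15.7 to 20.2, for the muscle actin gene Acta1 (0.994), at 39.0 FPKM, for mesothelium genes (0.851), at 81.1 FPKM, and for the epithelial keratin gene Krt19 (0.872), at 2.69 FPKM. Replicate 1 stood apart for extracellular matrix genes (0.960), with 1827 FPKM against 1420 to 1436. Replicate 3 stood apart for ribosomal protein genes (0.871), and replicate 4 for Igf1 (0.858), at 13.9 FPKM, and Ldha (0.960), at 77.6 FPKM.

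Hepatocyte genes were high in sHA-X replicates 3 and 4 alone. Sequencing depth is not the cause, since the deepest library had 1.26 times the reads of the shallowest while Alb ranged from 2.17 to 370.4 FPKM within the group. Reads carried over from another library may account for the low hepatocyte signal elsewhere, whose median share of the level in sHA-X replicate 4 was 3.33% in sHA-X replicate 2 and 1.36% in PBS replicate 2. The acinar genes of PBS replicate 2 had a median share of 0% in each other library, and the muscle genes of sHA-X replicate 2 of at most 1.52%, which leaves carry-over open because it can differ between pairs of libraries and because a spleen may express some muscle genes itself. An uneven presence of hepatocytes between spleens, or between the pieces of spleen that were sampled, was not tested.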

How the results depend on the processing

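The alternatives that left out both second libraries, and those that averaged sHA-X libraries, were chosen after seeing the data. Against 1108 higher and 600 lower genes, the counts with 1 library left out ranged from 488 to 1263 higher and from 228 to 637 lower. They were 492 and 330 without both second libraries, and with fewer values 521 and 191, 638 and 199, and 795 and 288 for sHA-X averaged as 1+2 and 3+4, 1+3 and 2+4, and 1+4 and 2+3. A fold of at least 2 gave 138 and 13 (149 and 14 at an unadjusted p). Limma-voom with quality weights on the recovered reads, which left out 13 genes above 0 in 1 library, gave 1922 and 1171; the cause was not tested. Pseudocount, filters, scaling and robust variance kept both counts within 1.5 times, and scaling moved the share of higher calls from 64.9% to 56.0% at the lowest.

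Deviations of libraries with the same replicate number correlated across genes at 0.15, -0.21 and -0.29. Those with different numbers correlated at -0.18 to 0.245. This gives no sign that the numbers pair the libraries, but so few pairs cannot exclude it. With the replicate number as a block, 276 genes were higher and 72 lower. In that fit sHA-X replicate 4 had no PBS library in its block and so added nothing to the group difference.

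With an estimated correlation the 4 lists had adjusted p = 0.64 (drug, glucose and cholesterol) and 0.43 (fatty acid); fry gave 0.061 (drug), 0.029 (glucose), 0.011 (fatty acid) and 0.073 (cholesterol). The glucose list had 0.057 with a filter of 1 CPM in 3 libraries and 50 reads. With 1 library left out, the glucose list ranged from 0.0037 to 0.071. The ribosomal list turned direction without PBS replicate 3 (adjusted p = 0.83), with a left-out range from 0.0031. The cause was not tested. Of 100 called named genes, 71 kept the call in each fit with 1 library left out and 29 lost it in at least 1; no called named gene reversed. The summed hepatocyte FPKM kept its direction (586.8 to 1112 FPKM higher), and on the log2 scale the exact permutation p was 0.086. Of the planned count tools only limma-voom was run, as the values are FPKM. Depth differed by 1.26 times, and how far this limits genes near 1 FPKM was not tested.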

Other observations

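The fit without both second libraries, the pathway tests and the tests of depth and of pairs of libraries were chosen after seeing the data. The test of Fgfbp3 was added too, but before its values had been looked at. Interferon response genes and genes of glycolysis were among the lists called higher that the report does not describe. Of 33 interferon response genes 7 rose, including Zbp1, Gbp2, Gbp5 and Iigp1 (9 adjusted over the list alone; camera adjusted p = 0.0025, and adjusted p = 0.67 with an estimated correlation). The list call was lost without PBS replicate 3 (0.22). Members that rose numbered 3 without PBS replicate 1, 4 without PBS replicate 2 and 11 without sHA-X replicate 2, and the calls of Gbp2, Gbp5 and Iigp1 were lost in 4, 4 and 2 of the 7 fits with 1 library left out (adjusted p up to 0.13, 0.10 and 0.070). Of 19 hypoxia and glycolysis genes 6 rose, including Aldoa, Ldha and Egln3 (0.011 and 0.64), but 1 rose without PBS replicate 1 and 0 without both second libraries, where camera gave 0.055. In the pairs of values that follow, the first is the adjusted p of camera and the second that with an estimated correlation. None of 28 oxidative phosphorylation genes passed limma (8 were higher at an unadjusted p under 0.05), although camera called the list higher (0.0040 and 0.64). Of 30 ribosomal protein genes only Rpl27 fell (0.047 and 0.82), a call lost in each of the 7 fits (adjusted p up to 0.10), and the list turned direction without PBS replicate 3 (0.83). Of 11 plasma cell genes Xbp1 rose (0.027 and 0.68), a call lost in 5 of the 7 fits (adjusted p up to 0.12). The summed FPKM of the list was 650.3, 816.4 and 965.9 in PBS replicates 1 to 3 and 1137, 2421, 1142 and 2568 in sHA-X replicates 1 to 4. The plasma cell call was lost without PBS replicate 1, sHA-X replicate 2 or sHA-X replicate 4 (adjusted p up to 0.078). None of 20 acinar genes passed limma (0 at an unadjusted p under 0.05), although camera called the list lower (0.00077 and 0.67), and the skeletal muscle list was not called (0.50). Of 22 immediate early and stress genes 4 rose and 5 fell (0.80), with a median of 0.07 and a mean of 0.06 on the log2 scale while the test pointed lower. The mesothelium list likewise had a median of 0.02 and a mean of -0.03, and 0 of its 10 genes passed limma (0 at an unadjusted p under 0.05). Only 2 female-biased liver genes were tested and neither passed. Among the 309 pathways 47 were called higher and 3 lower by camera, and 0 with an estimated correlation (12 at an unadjusted p under 0.05). The pathways called higher included the lysosome pathway, with 37 of 114 genes higher, and glutathione metabolism, with 21 of 47.

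The 7 libraries can be split into 3 and 4 in 35 ways. The labels gave 1708 changed genes and the other splits at most 1, so 1 of the 35 splits reached that number. This is the smallest share that 35 splits allow (0.0286), and it speaks against chance for the gene count only if the 7 libraries are independent. Every other split mixed PBS and sHA-X libraries, so a real group difference would add to its spread and lower its count. The same held for 1108 higher genes (1 of 35, at most 0 elsewhere) and 600 lower genes (1 of 35, at most 1 elsewhere). It did not hold for the list calls of camera. As many lists as the real 26 were called in 7 of the 35 splits, with a highest other value of 28. An unadjusted camera p as small as the real one came from 15 splits for drug metabolism (real 5.5e-06, smallest other 4.5e-26), 11 for glucose (0.017 and 1.4e-05), 9 for fatty acids (0.00052 and 8.1e-07) and 12 for cholesterol (0.0019 and 4.5e-09). For each of the 4 lists, all of these splits kept sHA-X replicates 3 and 4 in the same group. The smallest p for drug metabolism joined sHA-X replicates 3 and 4 with PBS replicate 1 against the other libraries. A camera p this small thus came only where these sHA-X replicates, in which hepatocyte genes were high, stayed together. Chance is not excluded for these 4 list calls.

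Within sHA-X, a group of genes put replicates 1 and 3 together and replicates 2 and 4 together. Genes lying over 0.5 apart on the log2 scale between pairs, and within 0.25 inside both pairs, numbered 218 for 1 and 3 against 2 and 4, 64 for 1 and 2 against 3 and 4, and 2 for 1 and 4 against 2 and 3. Among genes picked after their values were seen, Jchain was 736.5, 1661, 739.9 and 1812 FPKM in replicates 1 to 4, Ide 14.1, 30.6, 13.8 and 29.4 FPKM, and H2-Q7 10.5, 32.8, 8.06 and 36.4 FPKM. Depth is not the cause, since replicate 4 had 1.26 times the reads of replicate 2. The spread of the log2 ratio was taken over 6104 genes with at least 1000 reads in each library. It was 0.102 between replicates 1 and 3, 0.120 between 1 and 2 and 0.122 between 2 and 4. It was 0.138 between 2 and 3, 0.149 between 3 and 4 and 0.162 between 1 and 4. By this measure replicate 4 was nearest to 2 and replicate 3 nearest to 1, but 2 and 4 were no closer than 1 and 2.

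A genotype shared by replicates 2 and 4 may account for the steps at Ide. It was predicted that Fgfbp3, on the same chromosome 19, would be higher there than in the other 5 libraries, with other nearby genes unmoved. The lower of the pair was 1.05 times the highest other library (95% counting interval 0.83 to 1.33), and Btaf1, which lies between Fgfbp3 and Ide, also stood above the other 5 libraries, so the test leaves this open. The bound on the counting interval and the count of neighbours were added after the first result was seen, which had passed a looser bound. The prediction had taken Fgfbp3 for the neighbour of Ide, which the coordinates show it is not. If libraries of a pair shared an animal, cage or batch, the 4 libraries would hold less than 4 independent values.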
